A study of Mus musculus with 4 samples.

How the data were processed

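Open chromatin was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA. The samples were 4 libraries of wild-type mouse lung at E15.5, forming 1 group with replicate numbers 1 to 4. Per the labels' protocols, lungs were snap-frozen, 60000 nuclei were tagmented, and libraries were prepared with a commercial kit. The labels did not say whether the replicates came from separate embryos or litters, so every SD over libraries measured only the spread between these samples, which may be technical. With 1 group there was no contrast between conditions, and the tests compared gene groups within the tissue.

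The deposited data were 1 list of narrow peaks per library. FastQC 0.12.1, Trim Galore, Bowtie2 2.5.2, SAMtools 1.18, bedtools 2.31.0, MACS3 3.0.1, deepTools and build mm10 were named in the submitters' processing notes. The role, order and parameters of these tools were not given in the sources used here, and neither were duplicate removal, removal of artefact-prone regions, the shift of reads for the Tn5 cut or the effective genome size. Peak names inside the list of replicate 1 carried the French word for fresh, and those of replicates 2, 3 and 4 the word frozen. The fold enrichment deposited for each peak was the authors' ratio of summit pileup to background, with 1 added to each. It was used to rank peaks within a list, to compare median fold between libraries and to recover summit pileups, also compared between libraries. The deposited −log10 p and −log10 q values also described the peak summit, and the lowest −log10 q in a list ranged from 1.32 to 1.87. The deposited score was 10 times the −log10 q, cut to a whole number, and was not analysed further. The deposited summit offset was counted in bp from the start of a peak.

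Read totals were not analysed here, so depth was read from the peak values. Fold values under 15 were whole multiples of 1 step per library in 100% of peaks, within a tolerance of 0.02 steps. A Poisson model with the background given by that step returned the deposited −log10 p in 100% of those peaks, within 0.05. The background pileups recovered this way were 2.11, 2.62, 2.59 and 2.21 in replicates 1 to 4. Because p followed from fold in this way, ranking peaks by p gave the same order as ranking them by fold.

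Peaks on the 19 autosomes, X and Y were kept. Between 1245 and 1814 peaks per library lay on other contigs and were left out. Overlapping or adjoining peaks of the 4 lists were merged, and a merged region holding at least 1 peak of every library was called open in all 4. Gene positions came from an annotation of GRCm38.p6, the assembly that mm10 represents. It gave the start and end of 21887 protein-coding genes, and all 517 distinct genes of the 24 lists were matched by symbol. Strand, transcripts, exons and a genome sequence were not used here. Promoters were therefore replaced by windows of 1 kb either side of both annotated gene ends, which adds the 3′ end and misses internal promoters. A gene was called open when every library had a peak of its own in these windows. Distal regions lay more than 2 kb from either end of any protein-coding gene. They were counted within 100 kb of either gene end and given per 100 kb of DNA searched, to allow for gene length. These were departures from the plan, which named transcription start sites, exons, introns and numbers of regions per gene.

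The gene lists, tests, alternatives and rule for naming genes were fixed before the data were examined. Lists were compared with all other protein-coding genes by a two-sided Fisher exact test on open gene ends. Their mean distal density was compared with 100000 random lists matched on decile of gene number within 500 kb, in a two-sided permutation test whose smallest p is 1e-05. Both families of 24 tests were adjusted by the Benjamini-Hochberg method. Lung regulators were compared with regulators of other organs, and Hox paralog groups 1 to 5 with groups 9 to 13, by two-sided permutation or Fisher exact tests. Gene lists overlapped, with 40 genes in more than 1 list. Named genes were 11 fixed lung genes, the Hox genes, and from each list the members with the highest gene-end percentile, the most distal regions, or no gene-end peak in any library. The percentile was the rank of the strongest gene-end peak by fold within its own library, averaged over libraries. The peak's summit was not required to lie in the window.

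An earlier computation counted a gene as open when a merged region, rather than a peak of each library, touched its window. It was replaced after its results had been seen, because the plan had named a peak in each library. It changed the Hox comparison at gene ends, so both sets of values are reported. The alternatives were a q of 1e-05 or less, lists of equal length, leaving out each library, at least 3 of 4 libraries, gene-end windows of 0.5 and 2.5 kb, a reach of 50 kb, unmatched random lists, and other overlap rules. Matching on gene length, leaving out peaks wider than 10 kb, the merged-region rule, permutation within Hox clusters, the check of summits, random placement of regions and the 23 gene families were added after seeing the data. Motif content of distal regions and matching on CpG content needed a genome sequence and were not run.

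Code was tested on simulated data over the 21887 genes. Of 200 random lists of 25 genes, 4.5% reached an unadjusted p under 0.05 in the distal test and 3% in the Fisher test. Lists drawn in proportion to distal density were detected in 98% of cases, and lists drawn strongly towards open genes in 95%. These rates hold for 25 genes with a strong planted excess and do not give the power for smaller lists or weaker excesses. Lists made of runs of neighbouring genes reached that p in 29.5% of cases, so distal p-values for clustered genes are too small. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.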

Results

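Open chromatin was mapped in 4 libraries of whole wild-type mouse lung at E15.5, when airways are still branching. The series concerns a gene programme driven by HOXA5, a homeodomain transcription factor of lung mesenchyme, and its stated design was to define open regions. The libraries held 134503, 186199, 211678 and 192842 peaks on the assembled chromosomes, in replicates 1 to 4. Their median fold enrichment was 8.99, 3.86, 3.90 and 3.73. Replicate 1 thus had the fewest peaks and the highest enrichment. Of its peaks, 70.5%, 69.6% and 66.8% overlapped a peak of replicates 2, 3 and 4, and 47.1%, 40.7% and 41.6% of the peaks of those lists overlapped one of replicate 1, against 60.6% to 70.6% among replicates 2 to 4. Both directions depend on list length, and replicate 1 had the shortest list. The mean Jaccard index of bases was 0.335 over 3 pairs with replicate 1 and 0.537 over the other 3, but replicate 1 covered 78.6 Mb and the others 140.7 to 162.1 Mb, which lowers its index by size alone. Ranks of fold across regions open in all 4 libraries had a mean Spearman rho of 0.743 with replicate 1 and 0.886 among the others. These are correlations across regions, which are not independent replicates.

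**Figure D1:**
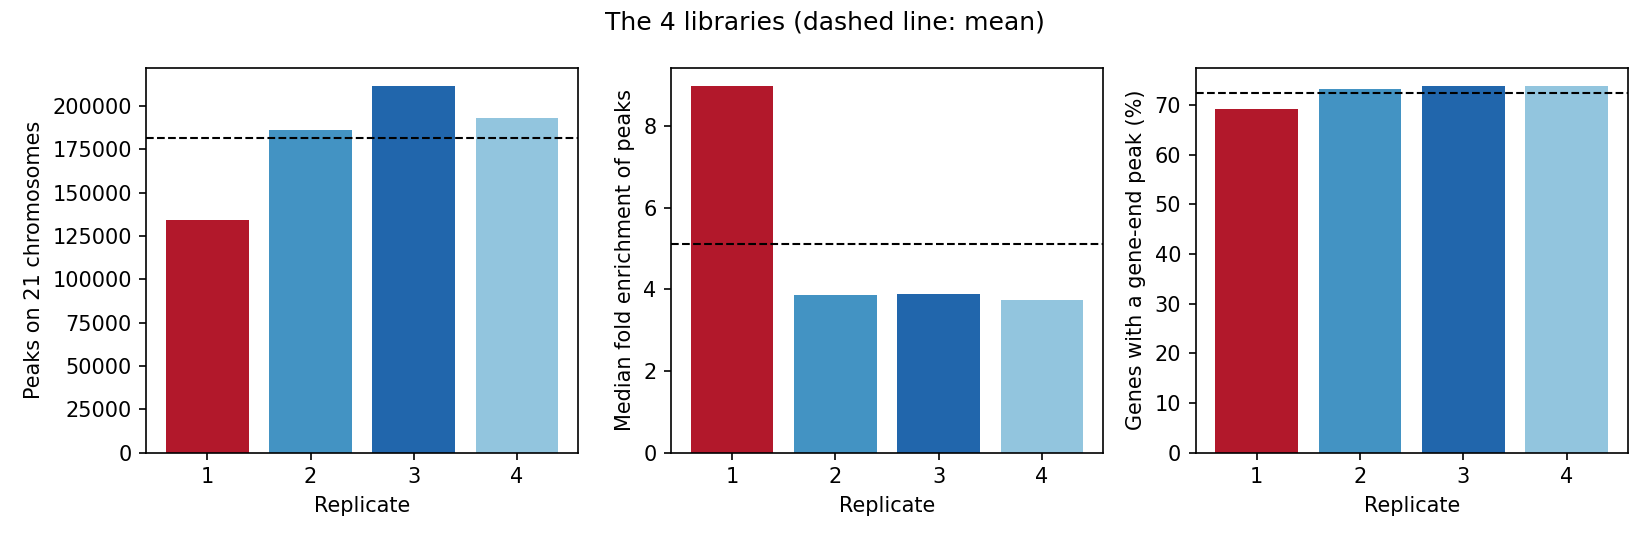
Peaks on 21 chromosomes, median fold enrichment of peaks, and percent of protein-coding genes with a gene-end peak, 1 bar per replicate, with the mean as a dashed line. Replicate 1 had 134503 peaks and a median fold of 8.99, against 3.73 to 3.90 in the other libraries.

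Merging gave 307572 regions, of which 66190 (21.5%) held a peak of every library. Another 152328 regions came from 1 library alone. Gene ends held 23.5% of the shared regions, against 6.11% when regions of the same widths were placed at random and 2.93% of bases. A further 39.9% lay elsewhere in gene bodies (37.2% at random) and 36.6% outside protein-coding genes (56.7% at random). In single libraries, 12.8% ± 0.531 (SD, n = 4) of peaks lay at gene ends. Of 21887 protein-coding genes, 14602 (66.7%) had a peak at an annotated end in every library. The same windows moved 25 kb outwards were open in 26.2% of genes. No library had a gene-end peak at 4876 genes. Ranks below are those of the strongest peak touching a gene's windows. Among 56 genes checked, that peak had its summit inside the window in all 4 libraries for 38. Ager, Apoa2, Cd68, Egfl7, Erbb3, Fgf10, Irx5, Klf1, Shh, Smtn, Srf and Tbx5 were among the other 18, so their ranks need not be the gene's own. Because windows cover both gene ends, even a summit inside a window need not lie at the gene's promoter and may belong to a neighbouring gene.

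Hoxa5, on chromosome 6 from 52201754 to 52204587 (mm10), was open in all 4 libraries. Its gene-end peak ranked at the 96.9th ± 0.27 percentile of fold (SD, n = 4). The neighbouring Hoxa6 shared that peak, and Hoxa4 ranked at 98.5 ± 0.41. The strongest distal region near Hoxa5, at 52174939 to 52177779, lay 23.98 kb from the gene and inside the annotated span of Hoxa3, at the 91.9th ± 1.60 percentile. In the Hox A cluster 10 of 11 genes were open, in Hox B 9 of 10, in Hox C 4 of 9 and in Hox D 3 of 9. Without replicate 1 these counts were 11, 10, 6 and 8, so the low count in Hox D rested on 1 library. Peaks covered 43.7% ± 5.30 (SD, n = 4) of the Hox A cluster and 36.7% ± 3.33 of Hox B. Coverage was 9.31% ± 4.13 in Hox C and 11.5% ± 6.65 in Hox D.

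**Figure D2:**
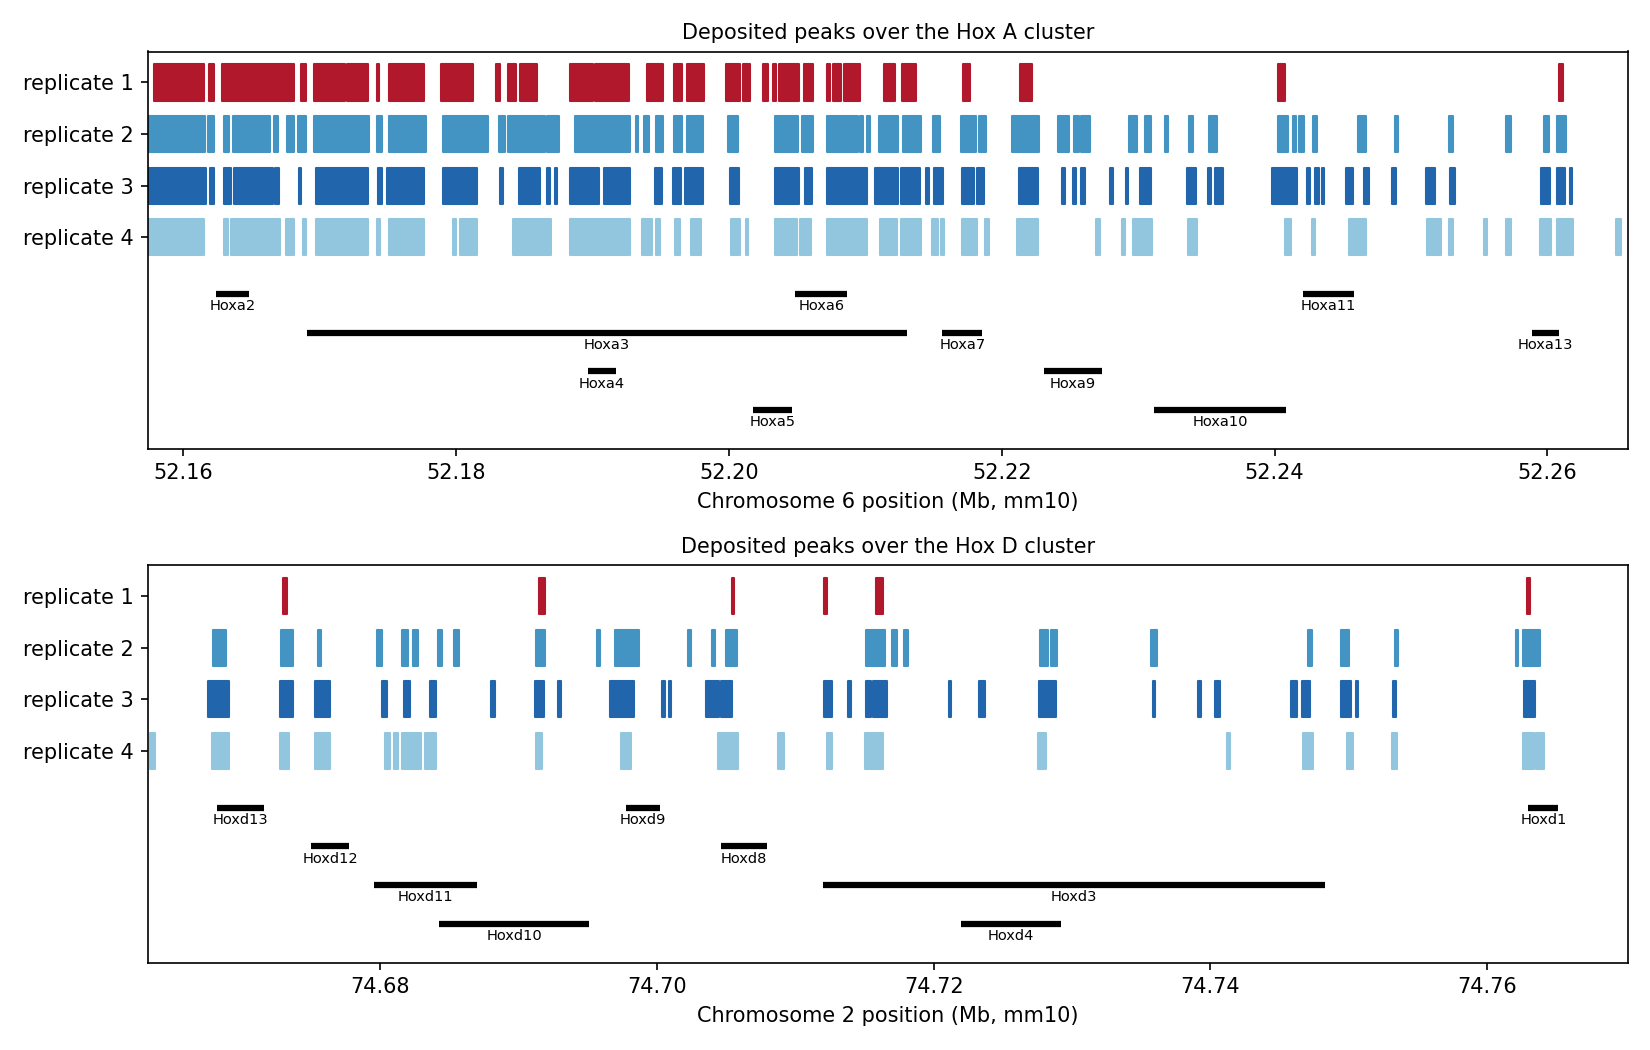
Deposited peaks of each replicate (coloured blocks) over the Hox A and Hox D clusters, with annotated genes as black bars and the position in Mb (mm10) on the x axis. Peaks were dense around Hoxa4, Hoxa5 and Hoxa6 in every library, while replicate 1 had few peaks over Hox D.

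**Figure D3:**
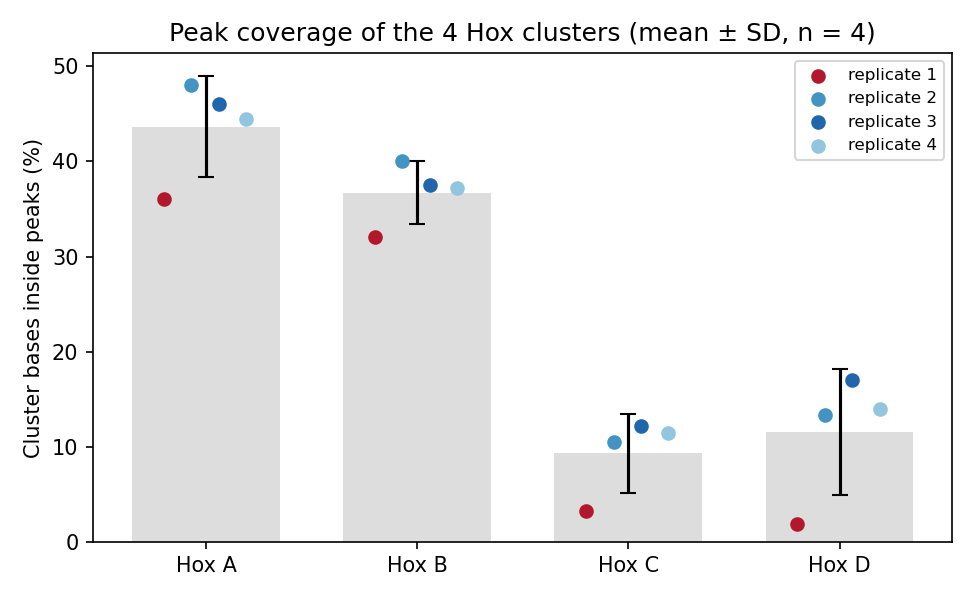
Percent of the bases of each Hox cluster inside peaks, with points for replicates, bars for the mean and whiskers for the SD (n = 4). Hox A and Hox B stood at 43.7% and 36.7%, above Hox C and Hox D, and replicate 1 was the lowest in each cluster.

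Position along the clusters was compared between paralog groups 1 to 5, at one end, and 9 to 13, at the other. Bases covered by peaks of all 4 libraries within 1 kb of gene ends averaged 1384 ± 1170 bp (SD over 15 genes) in groups 1 to 5 and 116 ± 217 bp (SD over 16 genes) in groups 9 to 13. The difference of 1268 bp gave p = 9e-05 in a two-sided permutation test, and without replicate 1 it was 1119 bp (permutation p = 0.00102). The groups are spread unequally over the clusters, so a difference blocked by cluster was also taken, with labels permuted within clusters. This blocked difference, not the same quantity as the 1268 bp, was 1005 bp (permutation p = 0.00071), or 836 bp without replicate 1 (permutation p = 0.00645). At gene ends, 13 of 15 and 6 of 16 genes were open (Fisher exact p = 0.00915, and permutation p = 0.0269 within clusters), but this call rested on replicate 1. Without it, 13 and 14 genes were open (Fisher exact p = 1, and permutation p = 0.536 within clusters). With 2.5 kb windows the counts were 14 and 11 (Fisher exact p = 0.172). Replicate 1 had peaks at 6 of the 16 genes of groups 9 to 13 and each other library at 15. Neighbouring Hox genes share windows and are not independent, so these p-values are too small. The merged-region rule computed earlier gave 13 and 7 open genes (Fisher exact p = 0.0233). Hoxa11, Hoxb13, Hoxd9, Hoxd10, Hoxd11, Hoxd12, Hoxd13 and Hoxc12 each had a gene-end peak in 3 libraries, Hoxc11 in 2 and Hoxc9 in 1. Over all 39 Hox genes 26 were open, which did not differ from other genes (Fisher exact adjusted p = 1). Without replicate 1 the Hox list stood above other genes (adjusted p = 0.0128, Fisher exact). Its distal density of 3.07 regions per 100 kb, against 2.68 in matched random lists, did not pass the permutation test (adjusted p = 0.464), though it passed within 50 kb (permutation adjusted p = 0.0399) and when lists were also matched on gene length (permutation adjusted p = 0.0369).

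Regulators and signals of lung mesenchyme were open at every member tested, 32 of 32 genes (Fisher exact adjusted p = 9.57e-05). They had 4.92 ± 2.81 distal regions per 100 kb (SD over genes), against 2.06 in matched random lists (permutation adjusted p = 4e-05). The list holds neighbouring Hox genes, among them Hoxb5 and Hoxb6 with equal gene-end ranks in every library, so both p-values are too small. Matching on CpG content was not run, so for this or any list the gene-end test cannot separate tissue from promoters open in most tissues. Housekeeping genes also passed it, with 24 of 25 open. Tbx2 and Tbx3, T-box transcription factors, ranked at the 99.6th ± 0.20 and 99.3rd ± 0.19 percentile (SD, n = 4). Gli2, a transcription factor of Hedgehog signalling, had 32 distal regions within 100 kb, and Tbx5, a T-box factor of early lung and limb buds, had 31. Foxf1 on chromosome 8 (121084386 to 121088154), a forkhead factor of mesenchyme, ranked at 96.7 ± 0.43 with 18 distal regions. Tbx4 on chromosome 11 (85886367 to 85916097) ranked at 95.6 ± 1.51, and its strongest distal region, at 85892303 to 85897346 inside the gene, ranked at 96.9 ± 1.54. Fgf10 on chromosome 13 (118714699 to 118792573), the growth factor that directs branching, ranked at 86.7 ± 2.63 and had 4 distal regions. Tbx5 varied more between libraries, at 82.4 ± 20.3, with 52.0 in replicate 1.

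Epithelial regulators and signals were open at 30 of 33 genes (Fisher exact adjusted p = 0.00538). Distal regions numbered 4.42 ± 2.82 per 100 kb, against 2.03 at random (permutation adjusted p = 4e-05). Etv5, a transcription factor downstream of FGF, ranked at 99.8 ± 0.01 with 25 distal regions, and Irx5 ranked at 99.4 ± 0.34. Fgfr2, the receptor for FGF10, had 28 distal regions and Foxp4 had 27. Nkx2-1 on chromosome 12 (56531935 to 56536908), the lineage factor of lung epithelium, ranked at 88.8 ± 7.87, and Foxa2 on chromosome 2 (148042877 to 148046969) at 94.4 ± 3.70. Sox9 on chromosome 11 (112782210 to 112787757), a factor of distal epithelial tips and of cartilage, ranked at 95.3 ± 1.55. Mycn on chromosome 12 (12936093 to 12941836) ranked at 95.7 ± 1.33. Shh on chromosome 5 (28456840 to 28467101), the epithelial Hedgehog ligand, ranged from 36.8 in replicate 1 to 96.5 in replicate 2. Trp63, a basal cell factor, had no gene-end peak in any library, while Ehf and Elf5 had one in 2 libraries each.

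Products of mature lung epithelium did not differ from other genes, with 15 of 20 open (Fisher exact adjusted p = 0.616) and 2.88 distal regions per 100 kb against 2.56 at random (permutation adjusted p = 0.612). Sftpc on chromosome 14 (70520941 to 70524081), encoding a surfactant protein, was open in every library at 97.0 ± 0.99. Its windows cover both gene ends, so this peak need not be at its promoter and may belong to a neighbouring gene. Rtkn2, expressed in alveolar type I cells, ranked at 98.3 ± 0.78, Ager was open in every library through a peak shared with Notch4 in replicates 3 and 4, and Aqp5 and Hopx each had 11 distal regions. Scgb3a2 and Sftpd had no gene-end peak in any library.

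All 18 HOXA5-linked genes collected from earlier literature were open (Fisher exact adjusted p = 0.00248), with 3.89 ± 1.63 distal regions per 100 kb against 2.19 at random (permutation adjusted p = 0.00357). Yy1 ranked at 99.3 ± 0.28 and Gata6 at 98.6 ± 0.64. Eln, encoding elastin, had 19 distal regions and Zbtb16 had 16. This list shares members with both lung regulator lists, so it is not independent of them.

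**Figure D4:**
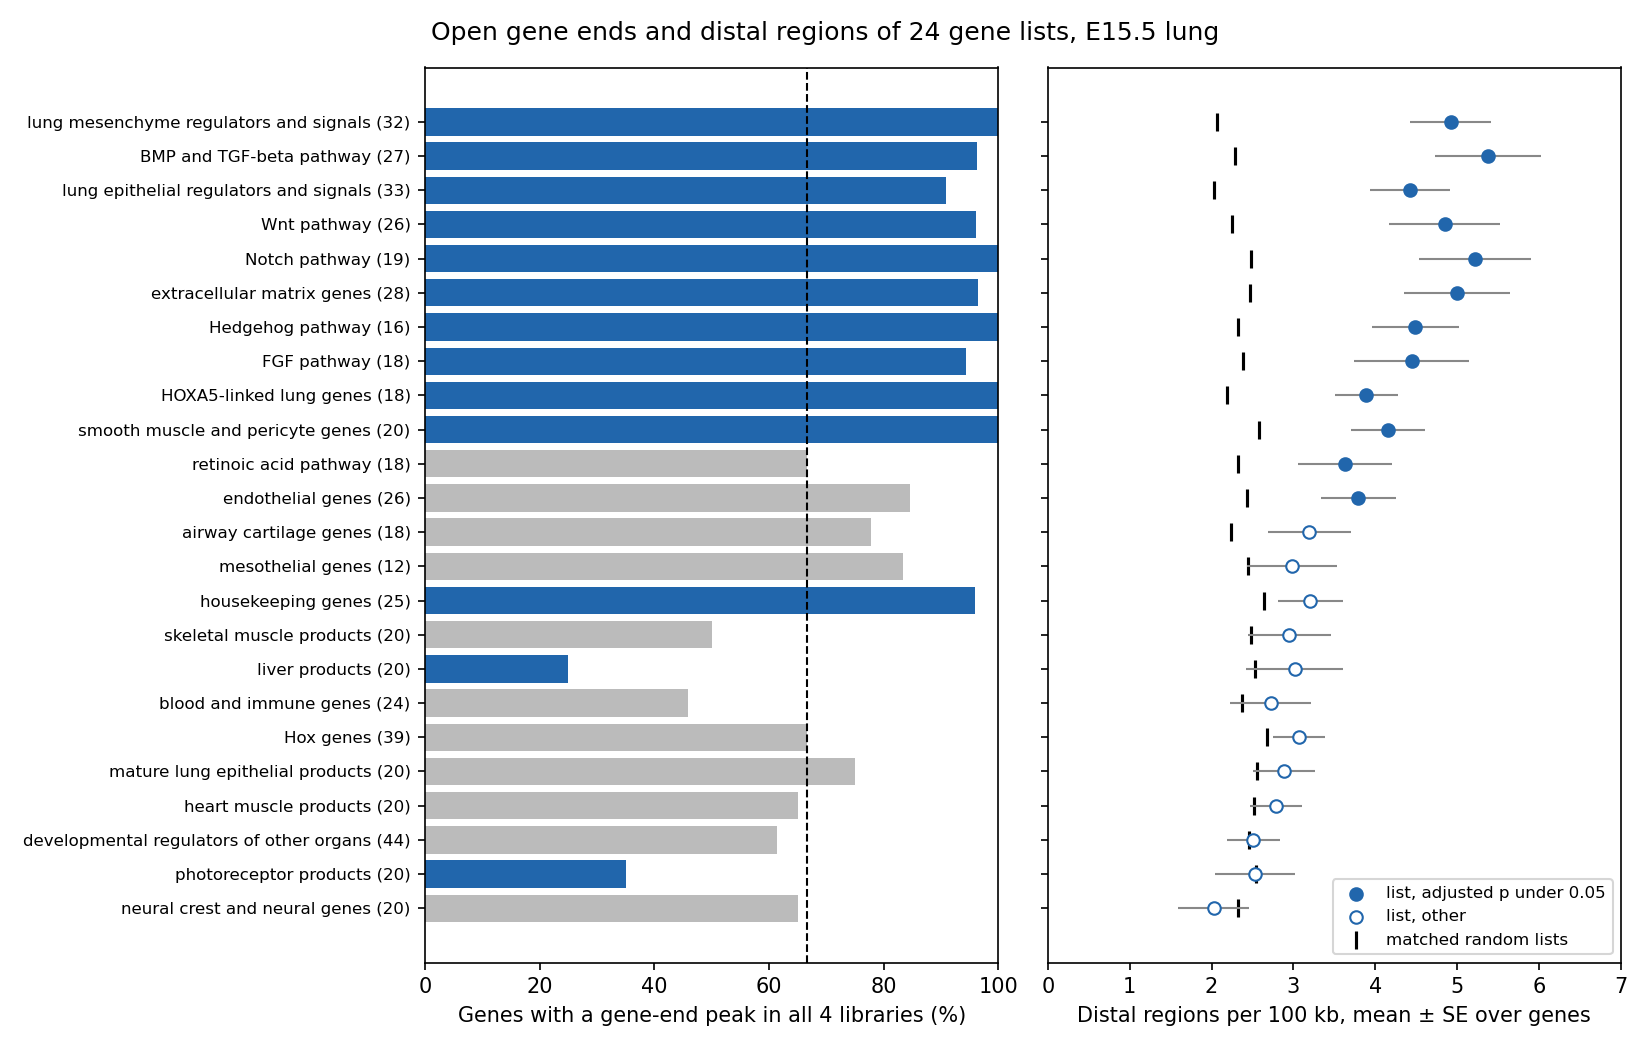
For 24 gene lists (number of genes in brackets), the left panel gives the percent of genes with a gene-end peak in all 4 libraries, blue where the adjusted p was under 0.05, with the 66.7% of all genes as a dashed line. The right panel gives distal regions per 100 kb (mean, whiskers for the SE over genes) beside matched random lists, from 5.38 in the BMP and TGF-beta pathway to 2.03 in neural genes.

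Among other lung cell types, smooth muscle and pericyte genes were open at 20 of 20 members (Fisher exact adjusted p = 0.00224) and had 4.15 distal regions per 100 kb against 2.58 at random (permutation adjusted p = 0.00465). Srf, a regulator of contractile genes, ranked at 99.5 ± 0.08 and Smtn at 99.0 ± 0.84, and Mylk had 23 distal regions and Abcc9 22. Endothelial genes passed only the distal test, at 3.79 against 2.44 per 100 kb (permutation adjusted p = 0.00465). At gene ends 22 of 26 were open (Fisher exact adjusted p = 0.0967), and Emcn had no peak in any library. Nos3 ranked at 96.9 ± 2.46 and Egfl7 at 94.1 ± 7.02, while Fli1 had 24 distal regions and Pecam1 23. With a q of 1e-05 or less the distal call was lost (permutation adjusted p = 0.0529), while the gene ends passed in 4 of 11 alternatives (Fisher exact adjusted p from 0.0256 to 0.316 over all 11), namely without replicate 2, with at least 3 of 4 libraries and with windows of 0.5 or 2.5 kb.

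Mesothelial genes passed neither test, with 10 of 12 open (Fisher exact adjusted p = 0.506) and 2.98 distal regions per 100 kb (permutation adjusted p = 0.511). Krt19 ranked at 95.6 ± 3.03, and Gata4 had 18 distal regions. Cartilage genes did not pass either, with 14 of 18 open (adjusted p = 0.605, Fisher exact) and 3.19 against 2.24 distal regions per 100 kb (permutation adjusted p = 0.0928), though the distal test passed within 50 kb (permutation adjusted p = 0.0409). Col11a1 ranked at 96.4 ± 0.46, Sox6 had 19 distal regions and Col9a1 had no gene-end peak. Neural genes were open at 13 of 20 members (Fisher exact adjusted p = 0.892) and had 2.03 distal regions per 100 kb (permutation adjusted p = 0.622). Erbb3 ranked at 99.96 ± 0.02 and Phox2a at 97.1 ± 1.58, and Sox10 had 14 distal regions. Blood and immune genes were open at 11 of 24 members, which did not pass (Fisher exact adjusted p = 0.0825). They stood below other genes in 7 of 11 alternatives (Fisher exact adjusted p from 0.0098 to 0.135 over all 11), among them a q of 1e-05 or less (0.0098), lists of equal length (0.0291) and leaving out replicate 1 (0.02) or replicate 2 (0.0495). Their 2.72 distal regions per 100 kb did not differ from random lists (permutation adjusted p = 0.511). Cd68 and the erythroid factor Klf1 ranked at 98.5 ± 0.34 and 96.5 ± 1.88 and Runx1 had 34 distal regions, while Adgre1 and Alas2 had no gene-end peak.

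Signalling pathways of the developing lung, except retinoic acid, passed both tests. Hedgehog genes were open at 16 of 16 members (Fisher exact adjusted p = 0.00538) and had 4.49 distal regions per 100 kb against 2.32 (permutation adjusted p = 0.000583). Sufu ranked at 99.6 ± 0.14 and Boc had 24 distal regions. Wnt genes were open at 25 of 26 (Fisher exact adjusted p = 0.00226) with 4.85 against 2.25 (permutation adjusted p = 4e-05). Fzd2, a Wnt receptor, ranked at 99.2 ± 0.13. Wls ranked at 99.94 ± 0.10, but through the last peak on chromosome 3 in every library. Tcf7l1 and Wnt11 had 32 and 31 distal regions. FGF genes were open at 17 of 18 (Fisher exact adjusted p = 0.0197) with 4.44 against 2.38 (permutation adjusted p = 0.00072), and Dusp6 ranked at 98.9 ± 0.02. BMP and TGF-beta genes had the highest density of any list, 5.38 against 2.29 (permutation adjusted p = 4e-05), with 26 of 27 open (Fisher exact adjusted p = 0.00222). Tgfbr3 had 41 distal regions and Smad3 38. Notch genes were open at 19 of 19 (Fisher exact adjusted p = 0.00248) with 5.21 against 2.48 (permutation adjusted p = 4e-05), and Hes1, a target of Notch, had 27 distal regions. Extracellular matrix genes were open at 27 of 28 (Fisher exact adjusted p = 0.00222) with 4.996 against 2.47 (permutation adjusted p = 4e-05). Col4a2 and Col4a1, neighbours that encode basement membrane collagen, had 43 and 42 distal regions, largely the same DNA. Retinoic acid genes passed only the distal test, at 3.63 against 2.32 (permutation adjusted p = 0.0194), with 12 of 18 open (Fisher exact adjusted p = 1). Rxra had 31 distal regions, and Rarb and Aldh1a1 had no peak at an annotated gene end. Without replicate 1 the retinoic acid distal call was lost (permutation adjusted p = 0.117), as it was with at least 3 of 4 libraries (permutation adjusted p = 0.0661). At gene ends the FGF call was lost with 2.5 kb windows (Fisher exact adjusted p = 0.0627), and the Notch call without peaks wider than 10 kb (Fisher exact adjusted p = 0.0572).

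Products of other organs were open less often or did not differ. Liver products were open at 5 of 20 genes (Fisher exact adjusted p = 0.00196), and Alb, Cyp2e1 and Cyp3a11 had no gene-end peak. Apoa2, at 99.8 ± 0.03, and Apoa1, with 15 distal regions, were open in every library. Photoreceptor products were open at 7 of 20 (Fisher exact adjusted p = 0.00792), and Arr3, Cnga1 and Cngb1 had no gene-end peak. With 2.5 kb windows the photoreceptor call was lost (Fisher exact adjusted p = 0.45). Skeletal muscle products, at 10 of 20, did not pass (Fisher exact adjusted p = 0.228), though with 0.5 kb windows they stood below other genes (Fisher exact adjusted p = 0.0178). Mylpf and Actn3 ranked at 99.8 ± 0.05 and 98.1 ± 0.62, while Myh1, Myh2 and Myh4 had no gene-end peak. Heart muscle products were open at 13 of 20 (Fisher exact adjusted p = 0.892), with Myl3 at 98.4 ± 0.32. The peaks of Mylpf, Actn3 and Myl3 need not be at their promoters and may belong to neighbouring genes. Distal density did not differ from random lists for liver, photoreceptor, skeletal or heart muscle products (permutation adjusted p = 0.472, 0.983, 0.472 and 0.64). Housekeeping genes were open at 24 of 25 (Fisher exact adjusted p = 0.00252), with Rpl13a at 99.86 ± 0.02, and did not differ in distal density (permutation adjusted p = 0.337), though they passed without replicate 1 (permutation adjusted p = 0.039) and with at least 3 of 4 libraries (permutation adjusted p = 0.0328). Without peaks wider than 10 kb the housekeeping call at gene ends was lost (Fisher exact adjusted p = 0.216).

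Lung regulators were compared directly with developmental regulators of other organs. The 64 lung regulators had 4.67 ± 2.83 distal regions per 100 kb (SD over genes) and the 44 others 2.51 ± 2.16. The difference of 2.16 gave p = 2e-05 in a two-sided permutation test and was 2.62 without replicate 1 (permutation p = 0.00073). Both sides hold neighbouring genes, so these p-values are too small. The lung lists include signals and receptors such as Fgf10 and Fgfr2, while the other list holds transcription factors. This test therefore cannot separate kind of gene from organ. The Wnt, Notch, BMP and TGF-beta and matrix lists also had densities above 4.67. The Hedgehog, FGF and retinoic acid lists had lower ones. Regulators of other organs were open at 27 genes (Fisher exact adjusted p = 0.626), and their distal density passed no threshold against random lists (permutation adjusted p = 0.918). With a q of 1e-05 or less they stood below other genes at gene ends (Fisher exact adjusted p = 0.0128), and without replicate 1 the odds ratio turned above 1 without passing (Fisher exact adjusted p = 0.0715). Nkx6-1 and Six2 ranked at 96.2 ± 1.26 and 92.1 ± 1.66, Cdx1 had 20 distal regions, and Crx, Hnf4a and Sry had no gene-end peak. The DNA searched for Cdx1 was largely that of its neighbour Pdgfrb, a lung mesenchyme gene with 18 distal regions. Regions there count on both sides of the comparison. Replicate 1 had gene-end peaks at 28 of these genes, and replicates 2, 3 and 4 at 39, 39 and 38.

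The genes with most distal regions within 100 kb were Zmiz1 (51), Sh3pxd2a (48), Fyn (46), Rad51b (46), Ablim1 (45), Col4a2 (43), Itga9 (43), Tspan9 (43), Uvrag (43) and Col4a1 (42). Most of them are long, and per 100 kb searched Timm22 (14.8), Spsb1 (14.7), Wnt11 (14.1), Sec14l1 (13.9) and Vegfa (13.5) were the densest. The distal region with the highest mean percentile of fold lay on chromosome 1 from 24611535 to 24616179, 23.6 kb from Col19a1. It was followed by chromosome 14 from 124801234 to 124802239, chromosome 7 from 145340929 to 145341454, 16.9 kb from Mrgprd, and chromosome 18 from 90601426 to 90602634. Of the 10 highest, 5 were the last shared region on their chromosome. Removal of artefact-prone regions was not stated, so none of the 10, including the chromosome 1 region, need mark open chromatin.

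Chromosome X held 7.80 regions open in all 4 libraries per Mb, below the range of the 19 autosomes (19.7 to 39.2, mean 26.9 ± 4.57 SD). Each such region needs a peak in every library, and replicate 3 had the fewest X peaks (2649). The low density was not confined to replicate 3. Chromosome X, of 170.9 Mb, held 2997, 6134, 2649 and 4848 peaks in replicates 1 to 4. Chromosome 3, of 159.9 Mb and with the lowest autosomal density, held 6917, 8137, 9475 and 8703. Replicate 3 had 6 peaks at the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, and the other libraries had none there. Over the whole of chromosome Y there were 57, 58, 103 and 66 peaks in replicates 1 to 4. X peaks per 100 autosomal peaks numbered 2.28, 3.41, 1.27 and 2.58 in replicates 1 to 4. At Xist, the RNA gene that silences one X chromosome in females, the strongest peak ranked at 82.2, 92.4, 64.6 and 93.0. No list held peaks on the mitochondrial chromosome.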

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

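Tests of depth, tissue state and sex were chosen after the results they bear on had been seen, and the test of gene-dense DNA before. Of 36 values compared across the 4 libraries, 12 had a library far from the rest. In 6 of these, 3 libraries were tied and 1 differed by 1 gene, so these show little and no chance rate holds for the total.

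Replicate 1 stood apart, with a median fold of 8.99, 87.7% of its peaks at a q of 1e-05 or less, and the fewest genes with a gene-end peak (69.2%). It also had the fewest open members among regulators of other organs (28), liver products (7), housekeeping genes (24), Hox genes (26), the Wnt pathway (25), the FGF pathway (17) and the BMP and TGF-beta pathway (26).

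For the higher fold and fewer peaks of replicate 1, lower depth as the whole cause was argued against, because it would lower the pileup of the same regions, and the median ratio of recovered summit pileup in shared regions was at least 1.95 over each other library. Lower depth beside another cause stays open, since background pileup was lowest in replicate 1, at no more than 0.955 times that of another library. Broad low background over gene-dense DNA in the other libraries is a candidate explanation, since regions they shared without replicate 1 had a median of 13 genes within 500 kb, 2.6 times that of regions of replicate 1 alone (5). Gene number also differed with the number of libraries sharing a region, and between sets of equal number the ratio was 1.8 to 2.2 for 1 library and 1.44 to 1.86 for 3. Fresh against frozen tissue cannot be told apart from the replicate, since 1 library carried the word for fresh, and no biological explanation was tested.

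Replicate 3 stood apart with 6 peaks at Y-linked genes and the fewest X peaks. Weaker calling was argued against, since its autosomal peaks numbered 1.26 times the mean of the other libraries. Every list held other peaks on chromosome Y, whose source was not examined. The 6 peaks, with none at these genes in the other libraries, would follow from male tissue in replicate 3 and female tissue in the others. The labels give no sex, so this stays a hypothesis.

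Extracellular matrix genes had the fewest open members in replicate 3 (27). Every list also held peaks on contigs outside the 21 chromosomes, with 1245 in the library with the fewest.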

How the results depend on the processing

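Matching on gene length, leaving out peaks wider than 10 kb, permuting within Hox clusters and the merged-region rule were chosen after seeing the data; the other alternatives were fixed before. The excess of distal regions near lung regulators over regulators of other organs kept its direction and side of the threshold in every alternative run (1.66 to 2.88 regions per 100 kb), as did the Hox difference in covered bases (725 to 2347 bp). For both lung regulator lists, the HOXA5-linked genes, smooth muscle and the Hedgehog, Wnt, BMP and TGF-beta and matrix lists, both tests kept their side in all 11 alternatives that can move each. Alternatives that cannot move a result by construction were left out. Over the remaining comparisons, 550 kept direction and side, 8 fell short of the threshold, 18 newly passed it, 37 changed direction and 24 moved in value. Motif content, CpG matching, and every alternative of the motif results were not run. Ranking by p moves nothing here. No paired analysis was possible because there is 1 group. Read totals were not used, so how far depth limits weak regions was not measured. Except where named, the cause of a change was not tested.

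The difference in open gene ends between Hox groups 1 to 5 and 9 to 13 was lost or turned in 3 settings. It was 49.2 percentage points, and −0.833 to 49.2 when 1 library was left out, the lowest without replicate 1. It was −0.833 with at least 3 of 4 libraries and 24.6 with 2.5 kb windows (Fisher exact p = 0.172). The merged-region rule, computed first, gave a Fisher exact p of 0.0233. Under that rule the Fisher exact p was 0.226 without replicate 1 or with at least 3 of 4 libraries, 0.22 with 2.5 kb windows, and 0.0659 with 0.5 kb windows or without regions wider than 10 kb.

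Regions open numbered 104316 in at least 3 of 4 libraries. Genes open were 63.7% with a q of 1e-05 or less, 63.5% and 71.6% with 0.5 and 2.5 kb windows, 71.5% with at least 3 of 4 libraries, and 67.0% to 70.4% without 1 library. Regions at gene ends were 30.3%, 22.0%, 27.8% and 18.0% in those settings, 25.7% with lists of equal length, and 19.9% to 22.3% without 1 library. Regions elsewhere in gene bodies were 36.1% (q of 1e-05), 37.4% (2.5 kb), 43.4% (at least 3 of 4) and 40.6% to 42.7% (without 1 library). Regions outside genes were 33.6%, 34.8% and 38.6% in the first 3 of these. The mean share of peaks overlapping another library was 34.1% with reciprocal overlap and 70.4% with a q of 1e-05 or less. Fewer or wider windows, and fewer libraries required, move these values by construction.

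Log2 odds ratios at gene ends that changed sign were, with at least 3 of 4 libraries, 0.55 for neural, 0.996 for other-organ, 0.55 for heart, 1.65 for Hox and 1.40 for retinoic acid genes. With 2.5 kb windows they were 0.16 for neural, 0.54 for heart, 0.78 for Hox and 0.81 for retinoic acid genes. Retinoic acid genes stood at 0.14 with 0.5 kb windows and 0.13 with a q of 1e-05, where mesothelial genes stood at −0.36. By merged region, heart stood at 0.021, Hox at 0.00052 and retinoic acid at 0.55. Without wide peaks, mature epithelial products stood at −0.063 and Hox at 0.062. Leaving out 1 library gave −0.058 to 1.73 for Hox, −0.38 to 1.07 for other organs, −0.18 to 0.62 for heart, −0.18 to 0.24 for neural and −0.087 to 0.89 for retinoic acid genes. Distal log2 ratios that changed sign were photoreceptor products (0.12 within 50 kb, 0.046 unmatched, 0.0079 without wide peaks), liver products (−0.073 with at least 3 of 4) and other organs (−0.076 with a q of 1e-05). Leaving out 1 library gave −0.018 to 0.21 for blood, −0.071 to 0.14 for other organs, −0.055 to 0.22 for liver and −0.031 to 0.037 for photoreceptor products.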

Other observations

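The gene families were chosen after the data had been seen, and the chromosome-end pattern was noticed there before its test was set. Of 23 families picked by symbol, 6 stood above other genes at gene ends and 8 below. Ribosomal protein genes were open at 71 of 72 members (Fisher exact adjusted p = 4.06e-11) and core histone genes at 55 of 57 (Fisher exact adjusted p = 1.74e-07). Semaphorins and plexins, guidance cues and their receptors, were open at 29 of 31 (Fisher exact adjusted p = 0.00212), Eph receptors and ephrins at 20 of 22 (0.0246) and Sox factors at 18 of 19 (0.0152). Laminins were open at 11 of 11 (Fisher exact adjusted p = 0.036, and 0.0674 without replicate 1) and had 2.14 times the distal density of matched random lists (permutation adjusted p = 0.000506). T-box genes had 1.89 times and collagen genes 1.63 times that density (permutation adjusted p = 0.000732 and 3.83e-05).

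Olfactory receptor genes were open at 10 of 1110 members and vomeronasal receptors at 4 of 353, with 1067 and 338 having no peak in any library. Cytochrome P450 families 2 and 3 were open at 9 of 54 (Fisher exact adjusted p = 2.09e-13), keratin-associated proteins at 2 of 56, beta-defensins at 2 of 42, keratins at 15 of 49 and chemokines at 18 of 37. Pax genes were open at 2 of 9 (Fisher exact adjusted p = 0.0171), but at 7 of 9 without replicate 1 (Fisher exact adjusted p = 1). Many of these families lie in runs of neighbouring genes, for which the p-values are too small.

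Among the 10 distal regions of highest fold, 5 were the last region on their chromosome, against 16 of all 48746 distal regions. Reads from repeated DNA collecting at chromosome ends may give such peaks. The 11 other distal regions that were last on their chromosome, which played no part in noticing this, had a median fold percentile of 99.8 among distal regions (53.7 to 99.97). This is what that explanation needs, but the repeat content was not examined and no biological explanation was tested. That explanation does not cover the chromosome 1 region of highest fold, which was not the last on its chromosome.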
